A study of Mauremys reevesii with 3 samples.

How the data were processed

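The data were 3 small RNA libraries from adrenal-kidney-gonad complexes of Chinese pond turtle embryos, 1 per incubation temperature (26, 29 and 32 °C), each made from pooled RNA of 3 biological samples, per the labels' protocols. Libraries were assigned to temperatures by the labels and to columns by the column names. The table gave the raw read count of each row in each library, per the file headers, and the same values as TPM, per the file headers. The deposited TPM equalled the count divided by the column total and multiplied by the same constant throughout, with no length term, in all rows within 0.01%. FastQC and Bowtie were named in the submitters' processing notes. The version of Bowtie, the genome build, the mismatches allowed, the miRNA reference and the treatment of reads that match several rows were not given in the sources used here. No genome was used, so no coordinates are given, and row names are those of the table, whose species prefix names the species of the reference sequence and not the animal.

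The depth was 9348882, 9624436 and 9613861 counts at 26, 29 and 32 °C, where 1 count corresponds to 0.107, 0.104 and 0.104 CPM (the count scaled to an equal total per library). These totals count a read more than once where it was assigned to several rows. The rule fixed before the data were examined counted rows of identical sequence and identical counts once. It merged 0 rows, since the 6 rows that had the sequence of another row differed from it in their counts, and all rows entered the main values. After the data were seen, rows sharing at least 16 consecutive bases on either strand were joined by single linkage, and the row with the highest count over the libraries stood for its sequence group. Distinct members of a family that share 16 bases are then taken as 1, and a named miRNA can be represented by a row of another name.

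Each pair of libraries was compared by the ratio of CPM on the table total, with a 95% exact conditional (Clopper-Pearson) interval for the 2 counts. No test across libraries was possible with 1 library per temperature, so no p-values are given. A row was called apart when the ratio was at least 2-fold and the interval excluded equality, among rows with at least 10 counts in either library of the pair. A count of 0 was set to a floor of 3 counts, and such ratios are bounds that leave out the counting error of the other count. No fold is given where both counts were at or under 3. The 29 and 32 °C comparisons with 26 °C share the 26 °C library, and their lists of rows were not compared for overlap.

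For 24 lists of miRNA families fixed before the data were examined, the median log2 ratio of CPM plus 1 was set beside those of 10000 random lists of the same size, matched on mean abundance in 10 bins. The lists were let-7, miR-17-92 and its paralogs, miR-15/16, miR-200, mesenchyme and smooth muscle, gonad, kidney, adrenal and steroidogenic, Hox cluster, germline and pluripotency, striated muscle, liver and pancreas, nervous system, erythroid, leukocyte, endothelial, cartilage, miR-29, miR-23/27/24, miR-181, the miR-183, miR-96 and miR-182 cluster, miR-99 with miR-100 and miR-125, miR-130 with miR-301 and miR-454, and a list of broadly expressed miRNAs (miR-26, miR-101, miR-103, miR-107, miR-148 and miR-152). Lists with fewer than 3 members received no percentile. Random lists drew members separately, so the percentiles take no account of strands of 1 hairpin moving together. Ratios of the 5p to the 3p strand used hairpins with at least 30 counts on each strand over the libraries, and their odds ratio between libraries was Fisher's conditional estimate with its exact interval.

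The miRNAs named in the text came from a rule fixed before the data were examined. It took, per pair of libraries, the 10 rows highest and the 10 lowest by the interval bound nearest to equality, the 10 most abundant rows, the 4 most abundant rows of each list, every row of miR-202 and miR-124, and the 5 strand ratios with the most certain difference. No miR-124 row was analysed here. The other members of lists named in the text, the strand ratio of miR-122 and rows of the same hairpin were chosen after their values were seen.

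Alternatives fixed before the data were examined were TMM factors of edgeR 4.0.16, size factors of DESeq2 1.42.0, a total without the most abundant row, the deposited TPM without an interval, other count minimums, other interval rules, a pseudocount of 10 CPM, summed counts of list members and thinning to the smallest total. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3. The ratio step was tested on simulated counts drawn from the pooled abundances, with 200 rows changed. For 32 over 26 °C, with 808 rows in the step, it called 96 of 100 rows changed 4-fold, 86 of 100 changed 2.5-fold and 10 of 614 unchanged rows. For 29 over 26 °C (810 rows) the calls were 91 of 100, 91 of 100 and 4 of 621, and for 32 over 29 °C (817 rows) they were 94 of 100, 89 of 100 and 6 of 623. No call went in the wrong direction. The simulation held sampling noise only, with no difference between embryos or dissections.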

Results

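Small RNAs were sequenced from embryos of the Chinese pond turtle (Mauremys reevesii), a species in which the temperature of the egg sets the sex of the hatchling, with mostly males from cool and mostly females from warm incubation. The tissue was the adrenal-kidney-gonad complex, the block of tissue that holds the embryonic gonad beside the adrenal gland and the kidney. Embryos came from eggs kept at 26, 29 or 32 °C and were taken at Greenbaum stage 16, when the gonad begins to respond to temperature. RNA of 3 biological samples per temperature was pooled into 1 library, so each temperature had 1 library and no difference below has a replicate check. The question was which microRNAs (miRNAs, short RNAs that repress messenger RNAs) differ in abundance between temperatures. The table listed 1743 rows, of which 1013 carried names of known miRNAs from 66 species prefixes and 730 were predicted entries. Its counts summed to 9348882 in the 26 °C library, 9624436 in the 29 °C library and 9613861 in the 32 °C library. Intervals of counts, shares and ratios and the floors given here cover counting error only, because each temperature had 1 library. Amplified reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error.

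Many rows stood for the same molecule. Of the 763 rows with at least 30 counts over the libraries, 429 shared at least 16 consecutive bases with another row whose counts lay within 10% in every library, and 114 shared them on the opposite strand with such a row. Rows joined by shared bases formed 973 sequence groups, and the most counted row of each group stood for it wherever a value is given per sequence group. The totals of these rows were 2969285, 3033734 and 2989977 counts at 26, 29 and 32 °C, so the table total exceeded them by factors of 3.15, 3.17 and 3.22. Counts of rows include such repeats, and counts per sequence group are given beside them.

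miR-148a and members of the miR-10 family were the most counted miRNAs at all 3 temperatures. miR-148a-3p (ggo-miR-148a) held 20.3% of the sequence-group total at 26 °C, 17.5% at 29 °C and 18.3% at 32 °C. It was followed by 3 miRNAs encoded in Hox clusters, with 497644, 501252 and 505146 counts of hsa-miR-10a-5p, 439596, 458331 and 500926 of mmu-miR-10b-5p and 228821, 257191 and 275280 of aca-miR-10c-5p at 26, 29 and 32 °C. The smooth muscle and mesenchyme miRNA miR-143 (ola-miR-143) had 156073, 197058 and 158077 counts. The 10 most abundant rows took 50.4% of the counts at 26 °C (exact Clopper-Pearson 95% interval 50.4% to 50.5%), 48.7% at 29 °C and 51.5% at 32 °C. By sequence group the 10 most abundant took 78.1%, 77.8% and 79.2%.

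Between the extreme temperatures, 32 and 26 °C, the gonad miRNA miR-202, the liver miRNA miR-122 and the pancreas miRNA miR-217 were lower in the 32 °C library. miR-202-5p (mmu-miR-202-5p), which vertebrate gonads express strongly, had 3140 counts at 32 °C against 7500 at 26 °C, a log2 ratio of -1.30 (95% interval -1.36 to -1.24), and its opposite arm miR-202-3p (dre-miR-202-3p) had 28 against 63, a log2 ratio of -1.21 (-1.91 to -0.55). miR-122-5p (cgr-miR-122), the main miRNA of hepatocytes, was lower in the 32 °C library with 1680 against 5629 counts and a log2 ratio of -1.78 (-1.86 to -1.71). miR-217 (hsa-miR-217) had a log2 ratio of -1.04 (-1.16 to -0.91). In the other direction, the epithelial miRNA miR-205-5p (oan-miR-205-5p) had 435 against 210 counts, a log2 ratio of 1.01 (0.77 to 1.25), and the neuronal miRNA miR-137-3p (dre-miR-137-3p) had 105 against 47, a log2 ratio of 1.12 (0.61 to 1.65). The miR-205 row was only just past 2-fold and was not the most counted row of its sequence group. Only 3 named sequence groups were at least 2-fold higher, 2 of miR-137 and 1 of the Hox cluster list, so miR-205 was not among them.

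By list, 7 of the 12 gonad-associated rows were at least 2-fold lower at 32 °C and none was higher. These rows belonged to miR-202 and miR-34 only, and the 3 of 5 sequence groups past 2-fold were all miR-202, 2 of them versions of its 5p strand named after different species. miR-34b-5p (gga-miR-34b-5p), of a family abundant in germ cells and ciliated epithelia, had 31837 against 45365 counts, a log2 ratio of -0.55 (-0.57 to -0.53). The gonad list's median was -0.98 over its 5 sequence groups, at percentile 0.61 of 10000 random lists matched on abundance. Random lists hold separate sequence groups, whereas this list and others hold strands and versions of 1 hairpin that move together, so percentiles describe a list's position and are not chances. The liver and pancreas list had a median of -1.40 over 4 sequence groups, at percentile 0.57, with 3 of the 4 lower. With TMM factors hsa-miR-217 stood at -0.82 (-0.95 to -0.70) and dre-miR-202-3p was just under 2-fold, which left 2 lower sequence groups in the liver and pancreas list and 2 in the gonad list. The Hox cluster list had a median of 0.14 over 13 sequence groups, at percentile 98.9, and its members included miR-196 (gga-miR-196-5p) with 5914 against 4115 counts, a log2 ratio of 0.48 (0.43 to 0.54). In the nervous system list 10 of 20 rows and 2 of 7 sequence groups were higher, both of them miR-137, and gga-miR-7 had 33098 against 21124 counts, a log2 ratio of 0.61 (0.58 to 0.63). Other members of that list went the other way, with mmu-miR-7b-5p at -0.52 (-0.61 to -0.44) and oan-miR-7-1-3p at -0.36 (-0.64 to -0.08), and its median of 0.16 at percentile 92.7 was not in the outer 5%. All 8 rows of the miR-183, miR-96 and miR-182 cluster, known from sensory epithelia, were lower, and all were miR-182. They formed only 2 sequence groups, the strands of miR-182, with 18 against 79 counts for aca-miR-182-3p and 14 against 38 for chi-miR-182. Among kidney miRNAs, ola-miR-192-5p had 25229 against 38237 counts, a log2 ratio of -0.64 (-0.66 to -0.62), while mmu-miR-194-5p, from the same cluster, stood at -0.11 (-0.16 to -0.06).

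Medians of the remaining lists are given per sequence group for 32 over 26 °C. They were 0.10 for let-7, -0.02 for miR-17-92 and its paralogs, -0.34 for miR-15/16, -0.23 for miR-200 and -0.02 for mesenchyme and smooth muscle. They were -0.38 for kidney, -0.37 for adrenal and steroidogenic, 0.13 for germline and pluripotency and -0.20 for striated muscle. They were -0.66 for erythroid, -0.10 for leukocyte, 0.03 for endothelial, 0.10 for miR-29 and -0.18 for miR-23/27/24. They were -0.40 for miR-181, -0.16 for the miR-99, miR-100 and miR-125 list, -0.15 for the miR-130, miR-301 and miR-454 list and -0.27 for the broadly expressed list that holds miR-101 and miR-148. The cartilage list had 0 rows with enough counts. The miR-200, germline and erythroid lists held 1 sequence group each. The adrenal list held 2, the strands of miR-24, which went opposite ways at 0.26 for hsa-miR-24-3p and -1.27 for chi-miR-24-5p. Its summed log2 ratio was 0.24 (0.15 to 0.32), opposite in sign to its median, so no direction is drawn for it. With TMM factors 19 of 69 list medians, taken over all rows and the 3 pairs, changed sign, so no direction is drawn from medians near 0.

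Of the 814 rows with at least 10 counts in either library, 36 were at least 2-fold higher and 108 at least 2-fold lower at 32 than at 26 °C with an interval that excluded equality, which came to 24 and 70 of 371 sequence groups. Of these groups, 23 higher and 55 lower ones had a mean under 10 CPM, and 0 had a mean over 1000 CPM. Predicted entries made up 22 of the higher and 58 of the lower rows. Per sequence group they made up 21 higher and 52 lower ones, beside 3 higher and 18 lower named ones. The most counted of these was novel_642, with 1805 counts at 26 °C, 512 at 29 °C and 121 at 32 °C, a log2 ratio of -3.94 (-4.22 to -3.67) for 32 over 26 °C. The entry novel_67 had 7, 285 and 168 counts, a log2 ratio of 4.54 (3.47 to 5.88). The entry novel_737 had 0, 37 and 42 counts, 13.6-fold higher at 32 °C when the 0 is set to 3 counts, with a lower interval limit of 3.40 in log2. The median log2 ratio of all 814 rows was -0.13 on the table total and 0.09 with trimmed-mean (TMM) factors, a shift against which small ratios such as those of the Hox and let-7 lists have to be read.

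**Figure D1:**
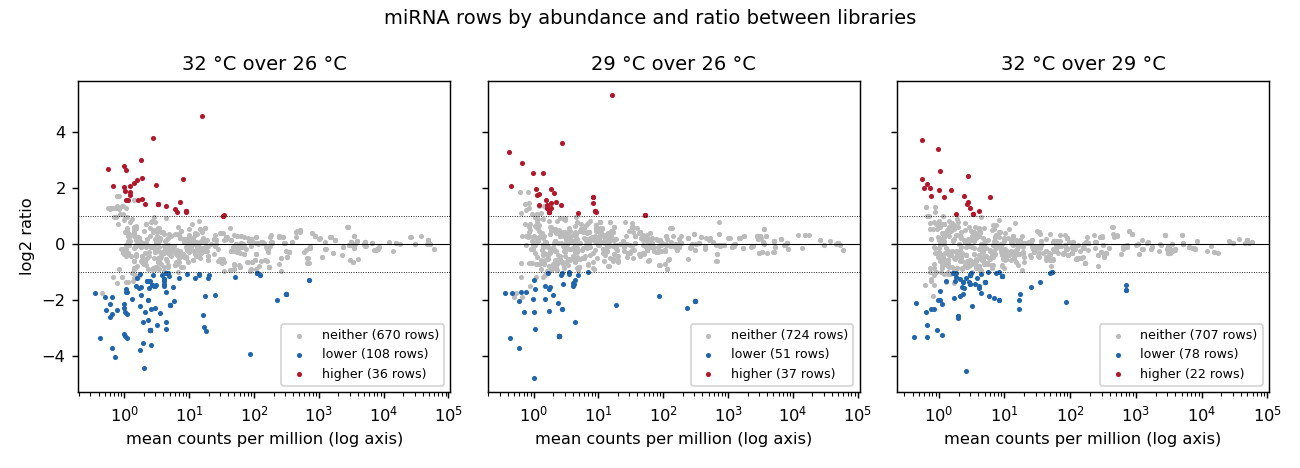
Each point is a row of the table with at least 10 counts in either library of the pair, plotted by its mean CPM (the count scaled to an equal total per library) over the 3 libraries (log axis) and its log2 ratio between the 2 libraries named above the panel. Rows at least 2-fold apart with a 95% interval that excludes equality are red (higher) or blue (lower), dotted lines mark 2-fold, and lower rows outnumber higher ones by 108 to 36, 51 to 37 and 78 to 22.

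Between 29 and 26 °C, both strands of miR-122 were lower and both strands of the leukocyte miRNA miR-223 higher in the 29 °C library, while miR-202 stayed below a 2-fold difference. miR-122-5p (cgr-miR-122) had 1410 counts at 29 °C against 5629 at 26 °C, a log2 ratio of -2.04 (-2.12 to -1.95), and its opposite arm hsa-miR-122-3p had 6 against 57, a log2 ratio of -3.29 (-4.79 to -2.08). miR-223-3p (hsa-miR-223-3p), the miRNA of granulocytes and monocytes, had 774 against 369 counts, a log2 ratio of 1.03 (0.85 to 1.21), and hsa-miR-223-5p had 150 against 46, a log2 ratio of 1.66 (1.18 to 2.17). The red-cell miRNA miR-451a (hsa-miR-451a) went the other way, with 9 against 44 counts and a log2 ratio of -2.33 (-3.55 to -1.28). miR-202-5p (mmu-miR-202-5p) had 9800 against 7500 counts, a log2 ratio of 0.34 (0.30 to 0.39).

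The leukocyte list had a median of 0.65 over 6 sequence groups, at percentile 99.6 of matched random lists, with 2 of the 6 at least 2-fold higher, both strands of the miR-223 hairpin. Its other members were below 2-fold, with log2 ratios of 0.77 (0.35 to 1.19) for dre-miR-146a and 0.67 (0.25 to 1.10) for aca-miR-142-3p, which is expressed in all blood cell lineages. The intervals of gga-miR-142-5p at 0.52 (-0.04 to 1.09) and xtr-miR-150 at 0.18 (-0.44 to 0.81) included equality. The liver and pancreas list had a median of -1.47 over 4 sequence groups, at percentile 0.07. The mesenchyme and smooth muscle list had a median of 0.27 over 13 sequence groups, at percentile 99.3, with none past 2-fold, and ola-miR-143 and dre-miR-145-5p, which share a cluster, stood at 0.29 and 0.28. The kidney list had a median of -0.26 over 12 sequence groups at percentile 4.82, outside the outer 5%, and 0 of the 12 were past 2-fold, with hsa-miR-30c-5p at -0.30 and xtr-miR-215 at 0.51. Of 812 rows tested, 37 were at least 2-fold higher and 51 lower, or 22 and 34 of 371 sequence groups. Predicted entries led the higher rows, with novel_67 at a log2 ratio of 5.31 (4.24 to 6.63). The entry novel_737 stood at 3.58 with its 0 set to 3 counts, with a lower interval limit of 3.21.

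Between 32 and 29 °C, miR-202 and miR-223 were lower in the 32 °C library. The log2 ratio was -1.64 (-1.70 to -1.58) for mmu-miR-202-5p and -1.93 (-2.59 to -1.32) for dre-miR-202-3p. The abundant predicted entry novel_16 followed the same order over the libraries, with 5993, 10646 and 3823 counts at 26, 29 and 32 °C and a log2 ratio of -1.48 (-1.53 to -1.42). hsa-miR-223-3p stood at -1.02 (-1.21 to -0.85) and hsa-miR-223-5p at -2.02 (-2.58 to -1.49), with 380 and 37 counts at 32 °C against 369 and 46 at 26 °C. miR-122-5p (cgr-miR-122) had a log2 ratio of 0.25 (0.15 to 0.36).

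The gonad list had a median of -0.81 over 5 sequence groups, at percentile 0.94, with 3 of the 5 lower, and the leukocyte list a median of -0.81 over 6, at percentile 1.23, with 3 of the 6 lower. With TMM factors hsa-miR-223-3p stood at -0.83 (-1.01 to -0.65) and aca-miR-142-3p moved from -1.14 (-1.62 to -0.68) to -0.95 (-1.42 to -0.48), both under 2-fold, which left 1 of the 6. The same factors moved dre-miR-202-5p, with 9 against 23 counts, from -1.35 (-2.65 to -0.19) to -1.15 (-2.45 to 0.01), still past 2-fold but with an interval that reached equality, which left 2 of the 5. The Hox cluster list had a median of 0.10 over 14 sequence groups, at percentile 98.5, with none past 2-fold. The pluripotency miRNA gga-miR-302d, also expressed in early germ cells, had 90, 135 and 102 counts at 26, 29 and 32 °C. Of 807 rows tested, 22 were at least 2-fold higher and 78 lower, or 18 and 50 of 371 sequence groups. Higher rows were 22.0% of those apart on the table total, 35.2% with TMM factors and 34.2% with median-of-ratios size factors, and the median log2 ratio of all rows was -0.18, 0.02 and -0.02 under the 3 scalings. In each pair of libraries 3 of the 17 lists with enough sequence groups had a median in the outer 5% of matched random lists.

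**Figure D2:**
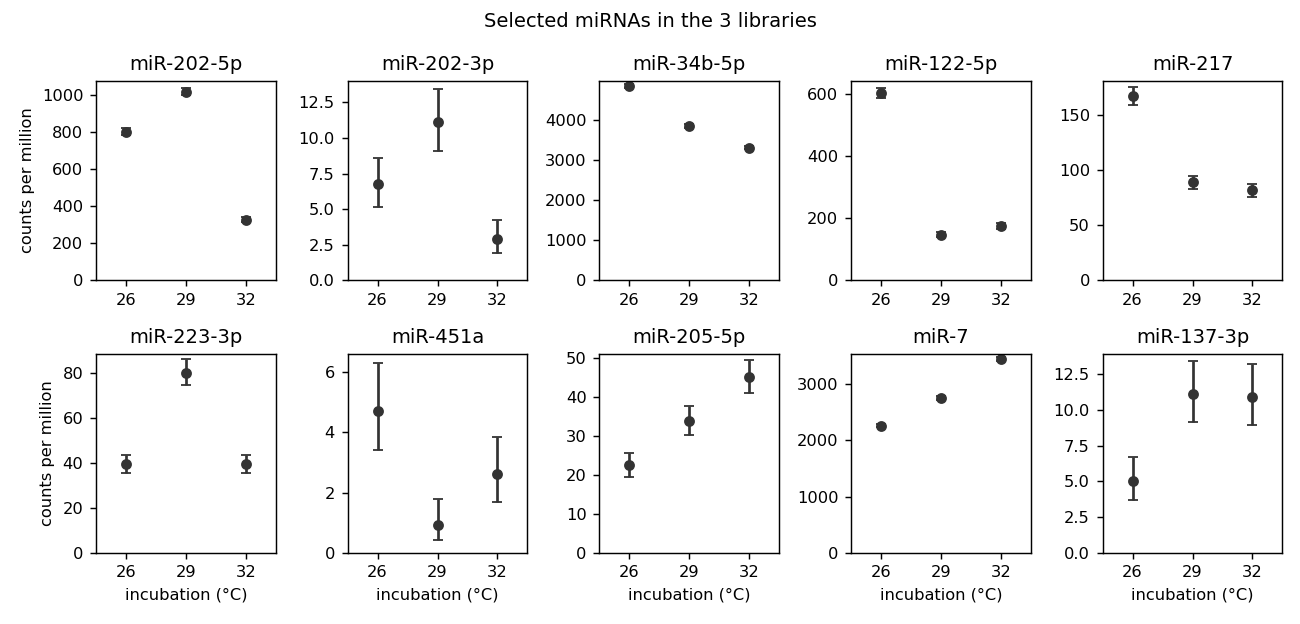
CPM (linear axis from 0) of 10 miRNAs against incubation temperature (°C), 1 pooled library per temperature, with bars for the exact Poisson 95% interval of the count. miR-202-5p had 802, 1018 and 327 CPM at 26, 29 and 32 °C, miR-122-5p 602, 147 and 175, and miR-223-3p 39.5, 80.4 and 39.5.

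**Figure D3:**
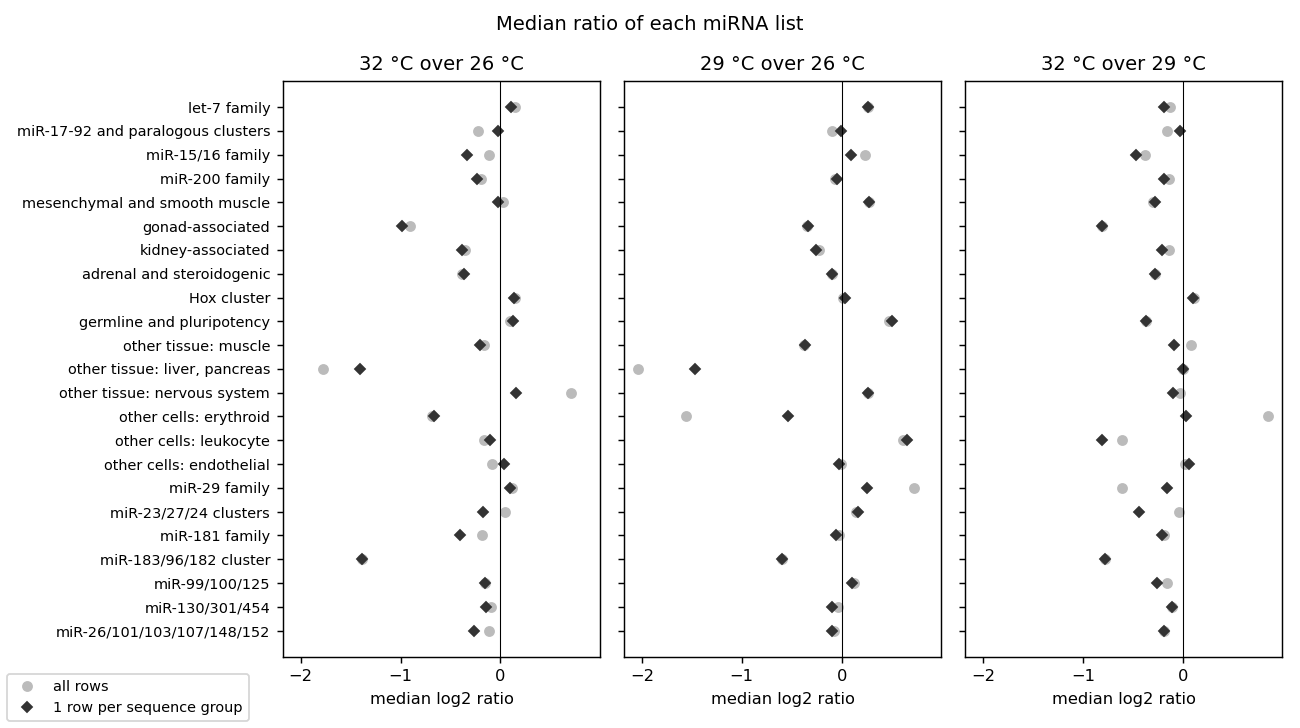
Median log2 ratio of the members of each miRNA list (rows of the plot) for each pair of libraries (panels), over all rows (grey circles) and over 1 row per sequence group (dark diamonds). The liver and pancreas list lies at -1.40 and -1.47 against the 26 °C library and at 0.00 between 32 and 29 °C, while the gonad-associated list lies at -0.81 between 32 and 29 °C.

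The order of the 3 libraries was taken from rows apart between 2 of them, a choice that by itself favours finding the remaining library in between, and no value expected without change was computed. Of the 144 rows at least 2-fold apart between 32 and 26 °C, 104 (72.2%) had their 29 °C value between the other values. The 32 °C value lay between the others in 55 of 88 rows apart between 29 and 26 °C (62.5%), and the 26 °C value in 52 of 100 rows apart between 32 and 29 °C (52.0%). Per sequence group these were 71 of 94 (75.5%), 29 of 56 (51.8%) and 37 of 68 (54.4%). Both gga-miR-7 and oan-miR-205-5p had a higher value in each warmer library, the latter with 210, 327 and 435 counts, whereas mmu-miR-202-5p was highest at 29 °C. Rows with at least 1 count numbered 1529 at 26 °C, 1532 at 29 °C and 1436 at 32 °C, or 1529, 1524 and 1428 after thinning to the smallest total. Rows with at least 10 counts numbered 756, 765 and 743.

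Ratios of the 5p to the 3p strand of the same hairpin do not depend on the scaling between libraries. Of 46 hairpins with at least 30 counts on each strand, 6 differed at least 2-fold in this ratio between 32 and 26 °C, 1 between 29 and 26 °C and 1 between 32 and 29 °C. Strands were paired by miRNA name, so reads of a strand may come from more than 1 hairpin, and a difference need not be a strand change. The largest certain difference was in miR-15c, of a family that restrains the cell cycle. There oan-miR-15c-3p had 218, 216 and 62 counts against 508, 644 and 435 for oan-miR-15c-5p. The log2 odds ratio was 1.59 (95% exact conditional interval 1.13 to 2.06) for 32 over 26 °C. The near-identical dre-miR-15b-5p had 514, 642 and 432 counts, so the 5p reads are not particular to miR-15c. In let-7c the log2 odds ratio was 1.69 (1.04 to 2.38), with 27 against 77 counts of hsa-let-7c-3p. It was -1.01 (-1.21 to -0.81) in miR-148a, -1.53 (-2.31 to -0.80) in miR-24 and -1.01 (-1.31 to -0.72) in miR-301a. In miR-122 the log2 odds ratio was 1.28 (0.14 to 2.66), on 7 counts of the 3p strand at 32 °C.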

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

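No paired analysis was possible because each temperature had 1 library, and with no replicates the limits below concern counting and processing only. The settings based on sequence groups, on named miRNAs only and on the sequence-group total were chosen after seeing the data. For 32 over 26 °C, 36 rows were higher and 108 lower. These counts became 17 and 53 with at least 50 counts, 7 and 47 with the whole interval beyond 2-fold, and 14 and 50 among named miRNAs only, while lower rows became 70 per sequence group under either total. For 29 over 26 °C, 37 higher and 51 lower rows became 12 and 23 with at least 50 counts, 7 and 23 with the whole interval beyond 2-fold, and 19 and 17 among named miRNAs only, while higher rows became 22 per sequence group under either total. For 32 over 29 °C, 22 higher and 78 lower rows became 5 and 28 with at least 50 counts, 4 and 19 with the whole interval beyond 2-fold, and 5 and 39 among named miRNAs only. Lower rows there became 46 with TMM factors, 48 with size factors, 50 per sequence group and 48 when these were scaled to their own total. The named rows apart repeat miRNAs under several species names. Whichever row stood for the group, they fell in 5 higher and 20 lower sequence groups for 32 over 26 °C. They fell in 6 and 5 for 29 over 26 °C and in 2 and 19 for 32 over 29 °C. Fewer rows tested or a stricter interval lower a count by construction, and the cause of the shift with scaling was not tested. Per sequence group, the share of the 10 most abundant became 78.1%, 77.8% and 79.2% at 26, 29 and 32 °C. Those detected numbered 838, 833 and 785 with at least 1 count and 326, 339 and 320 with at least 10. The number of lists in the outer 5% became 3, 3 and 3 for the 3 pairs, from 9, 12 and 8 over all rows. Among lists in the outer 5% over all rows, the median changed sign for miR-23/27/24 at 32 over 26 °C, to -0.011 with summed counts and -0.18 per sequence group, and for striated muscle at 32 over 29 °C, to -0.088 per sequence group; the cause was not tested. Over all lists and pairs, 19 of 69 medians changed sign with TMM factors, 12 with size factors, 11 with summed counts, 4 per sequence group, 0 with a pseudocount of 10 CPM and 6 of 62 with at least 50 counts. With at least 100 counts on each strand, 0 hairpins differed between 29 and 26 °C. Of the other counts of rows, those without a count filter, without an interval and without the most abundant row stayed within 1.5 times the main count. The count from TPM repeats the calculation without an interval and is not a separate check. The share of rows apart between 32 and 26 °C with 29 °C in between was 72.1% with TMM factors, 71.7% with size factors and 75.5% per sequence group. The sign of a ratio past 2-fold could not change under TMM or size factors, whose shifts were small, so it is no check. For 32 over 26 °C they moved miR-122-5p (cgr-miR-122) from -1.78 to -1.57 and -1.62. A row with 0 counts in a library allows up to 0.321 CPM at 26 °C and 0.312 at 29 and 32 °C.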

Other observations

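The test of GC content was chosen before its result was seen, and the tests of strand class, scaling, rare sequences, repeated counting, other organs and blood were chosen after the results were seen. Of the table total, in which a read can count more than once, predicted entries held 0.271% at 26 °C, 0.286% at 29 °C and 0.182% at 32 °C. No share of the sequence-group total was computed for these entries. Their summed log2 ratio for 32 over 26 °C was -0.58, and -0.54 without novel_16, the entry that followed miR-202 over the libraries. For 29 over 26 °C it was 0.08 with novel_16 and -0.24 without it, so the higher share at 29 °C rests on that entry. The sequence group with the most rows had 20, all predicted, whose counts summed to 1350, 1163 and 930 at 26, 29 and 32 °C, and novel_116 in it had 81, 34 and 10. These sums can count a read more than once, since novel_38 and novel_130, on opposite strands, both had 127, 116 and 88 counts. The less counted strand of a hairpin, which is mostly degraded after the duplex is loaded, was lower relative to its partner at 32 than at 26 °C in 31 of 46 hairpins, with a median log2 odds ratio of -0.16. The tally was also 31 of 46 for 29 over 26 °C and for 32 over 29 °C, and some hairpins repeat reads, such as miR-199a and miR-199b, so it is not particular to the extreme temperatures. A candidate explanation is that these strands as a class were lower at 32 °C, but their median log2 ratio of -0.29 over 44 sequence groups lay at percentile 17.3 of abundance-matched random lists of named miRNAs, whose median was -0.24. This neither separates the class from other miRNAs nor excludes a small difference.

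More rows were lower than higher in the 32 °C library than in the 26 °C library, 108 against 36. Scaling was not the whole cause, since only 34.1% of the rows apart were higher with TMM factors. GC content did not go with the log2 ratio over 371 sequence groups, which are not independent replicates (Spearman rho -0.034, 95% interval -0.14 to 0.07). A loss of rare sequences in the 32 °C library could not be excluded. The rho with abundance was 0.036 (-0.07 to 0.14), and medians from the rarest to the most abundant groups, split at 10, 100 and 1000 CPM, were -0.34, -0.14, -0.23 and -0.02, with no steady order. The groups below 0 made up 64.4%, 60.6%, 64.9% and 63.0% of these classes. These medians and shares are on the table total. TMM factors moved the median of all rows tested from -0.13 to 0.09, so the shares below 0 depend on the scaling. An effect of temperature stays open and untested.

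The hepatocyte miRNA miR-122 (cgr-miR-122) was 3.45-fold higher in the 26 °C than in the 32 °C library and 4.11-fold higher than in the 29 °C library. Scaling by the factors used was too small to explain this. It moved the log2 ratio for 32 over 26 °C from -1.78 to -1.57 under the scaling that brought it nearest to 0. Shifts of that size could not have brought it under 2-fold, so this is no separate check. For reads counted in several rows, hsa-miR-122-3p, whose sequence is separate from the 5p rows, had a ratio whose upper bound was -1.93. Its own counts of 57, 6 and 7 recur in other rows, such as mmu-miR-122-3p, so it cannot decide this point. It shows only that both strands were lower at 32 than at 26 °C. Liver and pancreas tissue in the 26 °C dissections is consistent with the list without miR-122, mainly hsa-miR-217 at 1567, 855 and 785 counts, whose summed log2 ratio was -1.02 (-1.15 to -0.90), although their level in kidney or gonad free of other organs was not analysed here. Some miRNAs of other tissues were also highest at 26 °C, with 766, 528 and 440 counts of mdo-miR-206 from striated muscle, a log2 ratio of -0.84 (-1.01 to -0.67), while dme-miR-133-3p of the same tissue stood at -0.14 (-0.31 to 0.03). An effect of temperature on these miRNAs within the complex, and chance between pools of 3, stay open and untested.

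The leukocyte list had summed counts of 657, 1300 and 649 at 26, 29 and 32 °C. The strands of miR-223 held 415, 924 and 417 of them, and the list without miR-223 had a summed log2 ratio of 0.59 (0.36 to 0.83) for 29 over 26 °C, so the difference rests mainly on 1 hairpin. Scaling moves all rows alike, and for 29 over 26 °C the median log2 ratio of 371 sequence groups was -0.031 (-0.06 to 0.02), which argues against it there. That interval comes from the ranked ratios of the groups, which are not independent replicates, and does not describe counting error. For 32 over 29 °C, TMM factors moved the summed log2 ratio from -1.001 (-1.14 to -0.86) to -0.80 (-0.94 to -0.67), under 2-fold but apart from equality, so scaling was not the whole cause. More whole blood in the 29 °C dissections would raise red-cell miRNAs with them, yet the erythroid list had 49, 20 and 28 counts and a summed log2 ratio of -1.33 (-2.16 to -0.56), against 0.94 (0.81 to 1.08) for the leukocyte list. This rests on hsa-miR-451a, with 44, 9 and 25 counts, since dre-miR-144-5p had 5, 11 and 2 and a log2 ratio of 1.10 (-0.55 to 2.97). White cells within the tissue or an attached lymphoid or blood-forming tissue may differ between the pools, and an effect of temperature stays open and untested.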
